A study of Mus musculus with 53 samples.

How the data were processed

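The data were RNA sequencing read counts per gene from 53 mouse liver libraries, 1 column per library. Per the labels' protocols, RNA was extracted from snap-frozen liver with column or bead kits, and directional polyA libraries were sequenced on a NextSeq 500. Per the submitters' processing notes, reads were aligned with STAR 2.7.0f to the GRCm38 mouse genome. The counts were deposited by the authors as whole numbers without normalization. The counting program, the annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here. Values of near-identical paralogs (major urinary proteins, Cyp2c enzymes, Serpina1 and Saa genes) and of overlapping or antisense genes are therefore uncertain.

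The table held 55536 Ensembl gene identifiers, of which 24990 had a count of 0 in every library. A symbol other than the identifier was found for 55450 of them in the GENCODE M21 annotation, and 86 had none; coordinates and gene types came from the same annotation. Every column of counts was mapped to a group (0 left over). Total counts per library ranged from 7.26 to 17.9 M with a median of 12.9 M. At 12 weeks, replicates 1 to 6 of each group held 10.6 to 14.5 M counts and replicates 7 to 10 held 7.26 to 10.5 M, so each 12-week comparison was also computed within both sets of replicates.

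Groups were taken from the titles: chow with vehicle (n = 10 and 8 at 12 and 24 weeks), MASH with vehicle (n = 10 and 7) and MASH with semaglutide (n = 10 and 8). The labels do not state that each library came from a different animal. Each was treated as an independent replicate, so the p-values measure differences against the spread between libraries. The libraries of each duration formed a separate cohort, so duration and cohort cannot be told apart.

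Differential expression was tested in R 4.3.3 with edgeR 4.0.16. For each cohort, genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 13606 genes at 12 weeks and 13548 at 24 weeks. Libraries were scaled by the trimmed mean of M values (TMM), and the 3 groups were fitted together with robust dispersions and the robust quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was said to rise, fall or change at an adjusted p under 0.05. Every adjusted p of a gene is from this test unless another tool is named. Fold changes used a prior count of 0.125. Levels are counts scaled to library size (CPM) on TMM-scaled library sizes, with the standard deviation (SD) between libraries. Differences between the durations were tested as interaction terms in a fit of all 6 groups, over 14546 genes. Principal components used the 2000 most variable genes on log2-CPM with a prior count of 2.

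Lists of genes for liver cell types, pathways and technical signals were fixed before the data were examined, with the comparisons, tests and alternatives fixed at the same time. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the data and with fry. The number of its genes past the threshold was counted over all genes tested and adjusted over the list alone. Genes for naming were selected by a fixed rule, and the text gives values for only some of those selected. The first part took the 5 largest rises and 5 largest falls per comparison among genes with an adjusted p under 0.05, a log2-CPM of at least 1 when averaged over libraries on the log scale, a symbol other than a predicted gene, clone or pseudogene name, and at least 8 in 10 libraries of the first group on the same side of the mean log2-CPM of the second. For differences between the durations, the condition on libraries was dropped. The second part was a set of genes followed in every comparison: Col1a1, Col3a1, Timp1, Acta2, Spp1, Gpnmb, Trem2, Cd68, Ccl2, Scd1, Fasn, Srebf1, Cidec, Cyp7a1, Hmgcr, Fgf21, Krt19, Mki67 and Glp1r. The third part took, per list described, up to 4 members past the threshold with the smallest p and up to 2 that went against the majority, and for technical lists the member with the highest level. Among genes that changed in MASH and in the other direction with semaglutide, 5 per direction with the smallest larger of both adjusted p-values were selected.

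The test was run on simulated counts drawn from the fitted means, dispersions and library sizes, with 200 genes changed by known amounts. The share recovered at 1.5-fold, 2-fold and 4-fold was 76.9%, 84.8% and 95.5% for MASH against chow at 12 weeks, and 66.7%, 86.6% and 100% for semaglutide against MASH at 12 weeks. At 24 weeks these shares were 35.8%, 70.1% and 98.5% for MASH and 26.9%, 80.6% and 98.5% for semaglutide. For the differences between the durations they were 29.9%, 67.2% and 89.4% for the MASH effect and 37.3%, 68.7% and 92.4% for the semaglutide effect. The share of calls that were false ranged from 2.16% to 7.04%. Each comparison was simulated once, with rises and falls drawn at random. The real comparisons of MASH with chow and of semaglutide with MASH called 19.7% to 61.8% of genes, far more than 200. These shares may therefore not hold for the real counts.

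The alternatives set before the counts were seen were median-ratio (RLE) and upper-quartile scaling, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, the replicate number as a block and 1 fit over all libraries. Added after seeing the data were each set of 12-week replicates alone, a term for these sets, leaving out each library in turn, a fit without 4 libraries set apart from their groups and a fit without chow replicates 5 and 7 at 24 weeks. A library was set apart when its median correlation with its group lay more than 5 median absolute deviations below the cohort's median (under 0.9579 at 12 weeks, where there was none, and under 0.9568 at 24 weeks). Overlaps of calls between comparisons that share libraries were set beside 20 simulations of unchanged groups and beside splits of the shared libraries. Permutation tests of single values were exact where a group held fewer than 10 libraries. No library was left out of the main comparisons.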

Results

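Liver gene expression was measured by polyA RNA sequencing in 53 libraries from mice with metabolic dysfunction-associated steatohepatitis (MASH) and from chow-fed mice. The MASH mice had received a diet that induces obesity and fatty liver disease, with steatohepatitis and fibrosis established by liver biopsy before treatment. They were then given vehicle or semaglutide, a GLP-1 receptor agonist, at 30 nmol/kg under the skin each day. The titles name treatments of 12 and 24 weeks, and the series text gives 20 to 24 weeks for the longer one. At 12 weeks there were 10 libraries each of chow with vehicle, MASH with vehicle and MASH with semaglutide, and at 24 weeks there were 8, 7 and 8. Total counts (M) were 7.75 to 13.6 in chow, 7.81 to 14.5 in MASH and 7.26 to 13.9 in semaglutide libraries at 12 weeks. The ranges at 24 weeks were 12.1 to 17.9, 12 to 17.4 and 7.7 to 15.3.

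The first principal component of the 2000 most variable genes held 54.8% of the variance and separated chow from MASH livers. Most semaglutide libraries lay between them, and 3 at 12 weeks (replicates 5, 6 and 10) lay within the range of MASH vehicle. The second component held 11% and separated the durations. The mean share of counts from mitochondrially encoded genes was 6.13%, 4.81% and 4.98% in chow, MASH and semaglutide libraries at 12 weeks, and 3.26%, 3.06% and 2.57% at 24 weeks. At 24 weeks, 4 libraries correlated less with their own group than the rest: chow replicate 7, MASH replicate 3 and semaglutide replicates 2 and 8. Glp1r, the receptor of semaglutide, had at most 18 counts in any library and was too low to test.

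**Figure D1:**
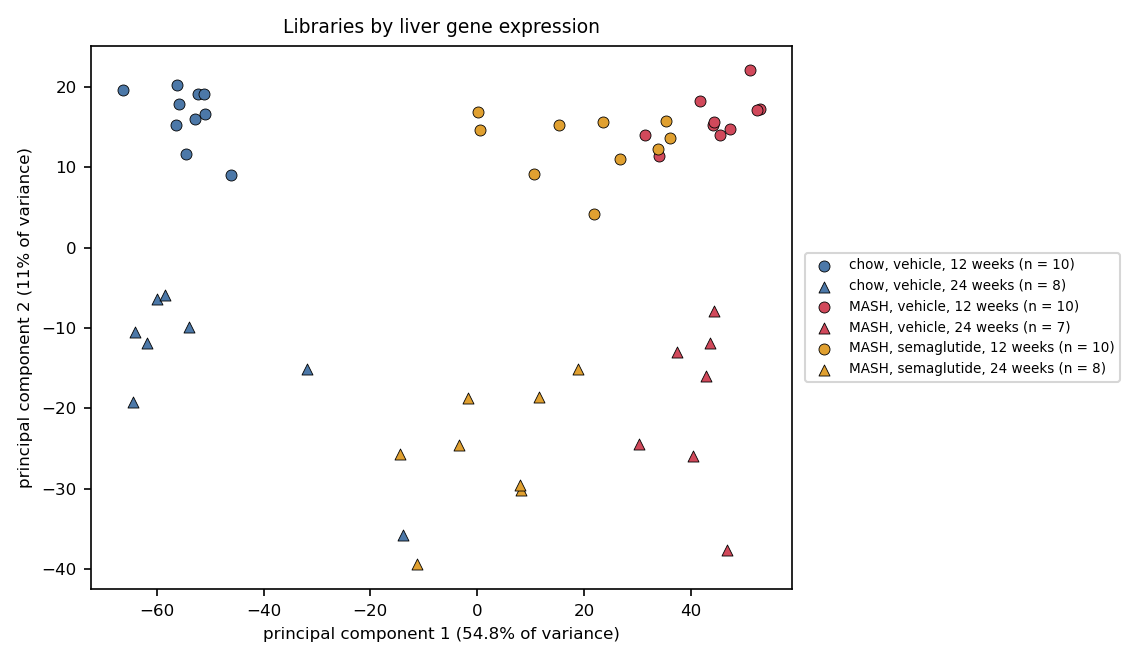
Each point is 1 library placed by principal components 1 (54.8% of variance) and 2 (11% of variance) of log2-CPM, with colour for chow, MASH vehicle and MASH semaglutide and shape for 12 or 24 weeks. Chow libraries lie to the left, MASH vehicle libraries to the right and most semaglutide libraries between. Semaglutide replicates 5, 6 and 10 at 12 weeks overlap MASH vehicle libraries, and chow replicate 7 at 24 weeks lies beside semaglutide libraries.

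The comparison of MASH with chow at 12 weeks asked how the diseased liver differed without the drug, both groups having received vehicle. The groups also differed in diet, so effects of diet and of disease cannot be told apart in any comparison with chow. Livers with MASH carried far more transcripts of scar matrix and of macrophages that gather around lipid, although neither list's camera call held with an estimated correlation (adjusted p = 0.0818 each). Col1a1, a chain of type I collagen, rose from 7.13 ± 3.14 to 179 ± 58.8 CPM (SD, n = 10 each), a log2 fold change of 4.67 ± 0.25 (SE, adjusted p = 2.9e-15). Gpnmb, a glycoprotein of lipid-laden macrophages, rose from 0.687 ± 0.654 to 151 ± 35.5 CPM (log2 7.81 ± 0.36, adjusted p = 1.41e-16). Timp1, an inhibitor of matrix-degrading enzymes, was at 0.0254 ± 0.0802 CPM in chow and 5.02 ± 1.94 CPM in MASH. At the same time Alb, the serum albumin gene, fell from 95100 ± 7140 to 35700 ± 5930 CPM.

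Of 32 fibrillar collagen and matrix genes, 31 rose and 1 (Fn1, log2 -0.26) fell, the same numbers adjusted over the list alone (camera adjusted p = 3.23e-17, and adjusted p = 0.0818 with an estimated correlation). The matrix turnover list had 16 of 18 higher and 1 lower, also adjusted over the list alone (camera 5.15e-07, adjusted p = 0.0884 with an estimated correlation), led by the macrophage elastase gene Mmp12 (0.687 to 84.3 CPM). Stellate cell and myofibroblast genes had 15 of 19 higher and 1 lower, also adjusted over the list alone (camera 2.65e-05, adjusted p = 0.0818 with an estimated correlation). Among them Pdgfrb, Vim and Cygb rose by log2 2.24, 2.25 and 2.21, while Acta2, the smooth muscle actin of myofibroblasts, was at 8.9 against 7.31 CPM (adjusted p = 0.151). For lipid-associated macrophages, 17 of 19 genes rose and 0 fell, as they did adjusted over the list alone (camera 3.46e-11, adjusted p = 0.0818 with an estimated correlation). Trem2 was at 26.2 against 0.501 CPM and Cd36 at 364 against 79.8 CPM. Monocyte and monocyte-derived macrophage genes had 12 of 13 higher, also adjusted over the list alone (camera 4.26e-08, adjusted p = 0.0884 with an estimated correlation), such as the chemokine receptor gene Ccr2 (log2 3.99). Resident Kupffer cell genes divided: 9 of 14 rose and 3 fell, also adjusted over the list alone (camera 0.00591, adjusted p = 0.374 with an estimated correlation). The complement gene C1qa rose by log2 1.74 and Cd5l by 2.33, and the scavenger receptor genes Cd163 and Marco changed by -6.30 and -3.11.

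All 14 dendritic cell and antigen presentation genes rose, also adjusted over the list alone (camera 7.64e-06, adjusted p = 0.155 with an estimated correlation). The class II genes H2-Aa and Cd74 were at log2 3.08 and 2.89. T and NK cell genes had 10 of 12 higher and 11 adjusted over the list alone (camera 0.0156, adjusted p = 0.302 with an estimated correlation). Chemokines and cytokines had 18 of 22 higher and 2 lower, also adjusted over the list alone (camera 1.51e-05, adjusted p = 0.0884 with an estimated correlation). The monocyte attractant Ccl2 was at 5.78 against 0.706 CPM. Type I interferon response genes had 20 of 21 higher and 1 lower, also adjusted over the list alone (camera 1.03e-05, adjusted p = 0.2 with an estimated correlation). Cholangiocyte and ductular genes had 15 of 17 higher, also adjusted over the list alone (camera 8.61e-05, adjusted p = 0.281 with an estimated correlation). Sox4 was at log2 2.44 and the bile duct keratin Krt19 at 2.13. Endothelial genes had 11 of 16 higher and 2 lower, and 11 and 3 adjusted over the list alone (camera 0.026, adjusted p = 0.405 with an estimated correlation). Of 24 cell cycle genes, 22 rose and 1 fell, also adjusted over the list alone (camera 6.49e-07, adjusted p = 0.0818 with an estimated correlation), and Mki67, a marker of dividing cells, went from 1.56 ± 0.74 to 18.3 ± 3.41 CPM. The oncofetal and liver tumour list had all 10 genes higher, also adjusted over the list alone (camera 0.000373, adjusted p = 0.131 with an estimated correlation), among them Ly6d (0.349 to 97.7 CPM). The p53 and cell death list had 14 of 19 higher and 1 lower, also adjusted over the list alone (camera 0.000525, adjusted p = 0.0818 with an estimated correlation).

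Hepatocyte identity genes fell in 16 of 18 and rose in 0, also adjusted over the list alone (camera 4.85e-09, adjusted p = 0.0818 with an estimated correlation). Pericentral genes had 10 of 15 lower and 1 higher (camera 0.000525, adjusted p = 0.108 with an estimated correlation) and periportal genes 11 of 15 lower and 1 higher (camera 1.29e-05, adjusted p = 0.122 with an estimated correlation), both the same adjusted over the list alone. Hal, the histidine-degrading enzyme of periportal cells, changed by log2 -2.35 and the pericentral Cyp2e1 by -1.32. All 24 cholesterol synthesis and uptake genes fell, also adjusted over the list alone (camera 2.53e-18, adjusted p = 0.0818 with an estimated correlation). Hmgcr, the rate-limiting enzyme of the pathway, was at 49.9 ± 17.8 against 226 ± 77.4 CPM and Idi1 at 2.33 against 46.5 CPM. Among cholesterol efflux genes 8 of 15 rose and 3 fell, also adjusted over the list alone (camera 0.0516). The sterol exporter Abcg5 was at log2 1.55. Bile acid genes had 16 of 22 lower and 2 higher, also adjusted over the list alone (camera 5.15e-07, adjusted p = 0.0818 with an estimated correlation). Slc10a1, the main bile acid importer of hepatocytes, went from 716 ± 57 to 179 ± 27.1 CPM, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 111 against 89.5 CPM (adjusted p = 0.429). Lipid droplet genes had 12 of 22 higher and 5 lower, also adjusted over the list alone (camera 0.0456, adjusted p = 0.302 with an estimated correlation). The droplet protein Cidec was at 74.1 ± 7.83 against 2.83 ± 2.14 CPM. De novo lipogenesis genes went both ways, 9 of 19 higher and 5 lower, also adjusted over the list alone (camera 0.946, with a median of 0.35 and a downward fry statistic): the desaturase Scd1 rose by log2 1.16 and fatty acid synthase Fasn was at 0.51 (adjusted p = 0.172). Fatty acid oxidation genes had 6 of 24 higher and 14 lower, 7 and 14 adjusted over the list alone (camera 0.058). Xenobiotic metabolism genes had 15 of 22 lower and 6 higher, also adjusted over the list alone (camera 0.000599, adjusted p = 0.155 with an estimated correlation). Among the largest changes was that of Hsd3b5, a male-biased steroid enzyme, at 0.136 against 97 CPM.

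In edgeR's quasi-likelihood test, 4243 genes rose and 4170 fell among 13606 (61.8%), of which 2205 and 550 changed more than 2-fold. Within replicates 1 to 6, 7164 genes passed, and within replicates 7 to 10, 5541 passed. Over the genes called in the full result, the log2 fold changes of these sets correlated with it at 0.992 and 0.979. The genes were chosen in the full result, of which each set is a part, so high values arise by construction. Camera called 28 of 41 lists and none held with an estimated correlation, while fry called 37.

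At 24 weeks the same question was asked in a separate cohort. Col1a1 rose from 6.58 ± 3.39 (n = 8) to 119 ± 33.6 CPM (n = 7), a log2 fold change of 4.18 ± 0.34 (adjusted p = 1.1e-09). Gpnmb was at 102 ± 21.6 CPM in MASH (log2 7.61 ± 0.37, adjusted p = 4.07e-13). Sqle, an enzyme of cholesterol synthesis, went from 171 ± 74 to 2.14 ± 0.394 CPM (log2 -6.30 ± 0.42, adjusted p = 7.07e-11). Timp1 was at 6.22 ± 2.56 against 0.118 ± 0.12 CPM and Acta2 rose by log2 0.89 (adjusted p = 0.00474).

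Of 32 matrix genes, 29 rose and 1 fell, also adjusted over the list alone (camera 8.86e-20, adjusted p = 0.0631 with an estimated correlation). The lists of matrix turnover (16 of 18 higher, 1 lower), stellate cells (16 of 19 higher) and lipid-associated macrophages (17 of 19 higher) had the same numbers adjusted over the list alone. The camera adjusted p-values were 1.16e-10, 3.45e-08 and 2.34e-13, and 0.0365, 0.0365 and 0.0387 with an estimated correlation. Monocyte-derived macrophage genes had 11 of 14 higher, also adjusted over the list alone (camera 7.17e-09, adjusted p = 0.101 with an estimated correlation). The receptor Cx3cr1 was at log2 4.25. Kupffer cell genes had 8 of 14 higher and 1 lower, 8 and 2 adjusted over the list alone (camera 0.0044, adjusted p = 0.442 with an estimated correlation), and the gene that fell was Cd163 (log2 -4.89). Dendritic cell genes had 12 of 14 higher, also adjusted over the list alone (camera 2.29e-07, adjusted p = 0.0807 with an estimated correlation). Chemokines had 16 of 22 higher and 2 lower, 17 and 2 adjusted over the list alone (camera 5.49e-07, adjusted p = 0.105 with an estimated correlation). T and NK cell genes had 8 of 14 higher and 9 adjusted over the list alone (camera 0.000846, adjusted p = 0.362 with an estimated correlation), and 13 without chow replicates 5 and 7 at 24 weeks. Type I interferon genes had 5 of 21 higher and 1 lower, also adjusted over the list alone (camera 0.000839, adjusted p = 0.458 with an estimated correlation). These became 18 higher and 0 lower without chow replicate 7 alone, in which the list's median level lay 3.26 log2 units above the mean of the 6 chow libraries other than replicates 5 and 7. Cholangiocyte genes had 12 of 16 higher and 1 lower, also adjusted over the list alone (camera 5.24e-05, adjusted p = 0.237 with an estimated correlation), and endothelial genes 8 of 16 higher and 1 lower, also adjusted over the list alone (camera 0.0076, adjusted p = 0.261 with an estimated correlation).

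Cell cycle genes had 20 of 23 higher and 1 lower, 21 and 1 adjusted over the list alone (camera 3.23e-12, and 0.0365 with an estimated correlation). Mki67 was at 13.6 ± 2.38 against 1.98 ± 1.75 CPM. Oncofetal genes had 10 of 12 higher, also adjusted over the list alone (camera 2.29e-07, and 0.0387 with an estimated correlation). The p53 list had 9 of 19 higher and 2 lower, 10 and 2 adjusted over the list alone (camera 0.00266, adjusted p = 0.0631 with an estimated correlation). The cell cycle inhibitor Cdkn1a was at log2 2.61. Hepatocyte identity genes fell in 15 of 18, and in 16 adjusted over the list alone (camera 2.58e-06, and 0.0387 with an estimated correlation). Alb was at 41700 ± 5240 against 99000 ± 8600 CPM. Pericentral genes had 9 of 15 lower and 1 higher (camera 0.000644, adjusted p = 0.151 with an estimated correlation) and periportal genes 9 of 15 lower (camera 0.000644, adjusted p = 0.0807 with an estimated correlation), both also adjusted over the list alone. All 24 cholesterol synthesis genes fell, also adjusted over the list alone (camera 2.46e-23, and 0.0338 with an estimated correlation). Hmgcr was at 30.5 ± 5.72 against 164 ± 65.4 CPM. Bile acid genes had 16 of 22 lower and 2 higher, also adjusted over the list alone (camera 9.3e-05, adjusted p = 0.0524 with an estimated correlation). Slc10a1 was at 167 ± 31.1 against 668 ± 128 CPM. Lipid droplet genes had 9 of 22 higher and 3 lower, 10 and 3 adjusted over the list alone (camera 0.00304, adjusted p = 0.225 with an estimated correlation), and Cidec was at 98 ± 24.1 against 3.15 ± 1.75 CPM. De novo lipogenesis genes had 5 of 19 higher and 6 lower, 6 and 6 adjusted over the list alone (camera 0.95), with a median of 0.10 and a mean of -0.02, and Scd1 rose by log2 1.31. Efflux genes had 6 of 15 higher and 2 lower, also adjusted over the list alone (camera 0.0594), and oxidation genes 3 of 24 higher and 11 lower, also adjusted over the list alone (camera 0.365). Xenobiotic genes had 5 of 22 higher and 11 lower, 7 and 11 adjusted over the list alone (camera 0.0353, adjusted p = 0.458 with an estimated correlation).

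In the edgeR test of MASH vehicle against chow vehicle at 24 weeks, with 13548 genes, 2928 rose and 3168 fell (45%), and 1848 and 593 changed more than 2-fold. Upper-quartile scaling shifted the median of all genes by 0.13 on the log2 scale and gave 3456 higher and 1905 lower (64.5% higher against 48%). Camera called 27 of 41 lists, 7 of them also with an estimated correlation, and fry called 31.

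**Figure D2:**
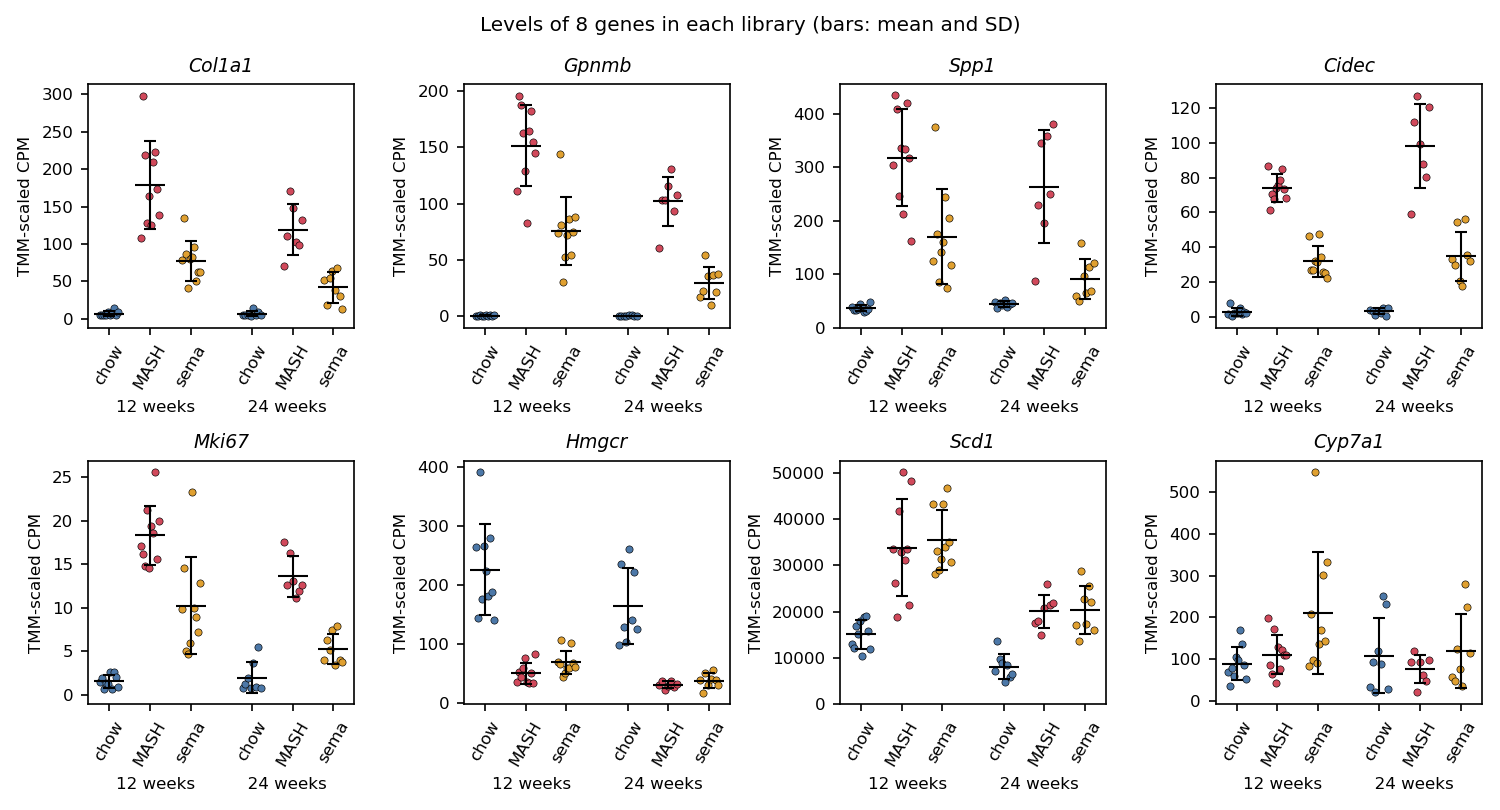
TMM-scaled CPM (vertical axis, linear from 0) of 8 genes in each library of chow vehicle (chow), MASH vehicle (MASH) and MASH semaglutide (sema) groups at 12 and 24 weeks, with bars for the mean and SD. Col1a1, Gpnmb, Spp1, Cidec and Mki67 lie highest in MASH and lower with semaglutide (Col1a1 179 and 77.5 CPM at 12 weeks), while Hmgcr lies highest in chow (226 and 164 CPM) and the Scd1 means of MASH and semaglutide are alike (20100 and 20400 CPM at 24 weeks).

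Semaglutide was compared with vehicle in MASH mice at 12 weeks to find what the drug changed in the diseased liver. Most transcripts of the matrix and lipid-associated macrophage lists were lower and most of the hepatocyte identity list higher, although no camera call of these lists held with an estimated correlation (adjusted p = 0.0516 each). Col1a1 fell from 179 ± 58.8 to 77.5 ± 26.4 CPM (n = 10 each), a log2 fold change of -1.21 ± 0.20 (adjusted p = 9.44e-05), and Gpnmb from 151 ± 35.5 to 75.8 ± 29.8 CPM (log2 -1.003 ± 0.219, adjusted p = 0.0014). Cidec fell from 74.1 ± 7.83 to 31.9 ± 8.79 CPM (log2 -1.21, adjusted p = 3.24e-05). Slc10a1 rose from 179 ± 27.1 to 392 ± 102 CPM, a log2 fold change of 1.13 ± 0.11 (adjusted p = 1.26e-08).

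Of 32 matrix genes, 27 fell and 1 (Fn1) rose, and 31 and 1 did so adjusted over the list alone (camera 5.3e-24, adjusted p = 0.0516 with an estimated correlation). Matrix turnover genes fell in 14 of 18, also adjusted over the list alone (camera 4.05e-08, adjusted p = 0.0974 with an estimated correlation). Timp1 was at 2.35 ± 0.734 and Mmp12 at 38.7 ± 10.1 CPM. Stellate cell genes fell in 5 of 19, also adjusted over the list alone (camera 0.00336, adjusted p = 0.152 with an estimated correlation), and Acta2 was at 8.57 against 8.9 CPM (adjusted p = 0.856). Lipid-associated macrophage genes fell in 17 of 19 and rose in 1 (Apoe, whose call was lost under RLE, upper-quartile, blocked and joint fits), also adjusted over the list alone (camera 1.02e-14, adjusted p = 0.0516 with an estimated correlation). Spp1, the osteopontin gene, was at 170 ± 89.1 against 318 ± 90.8 CPM, Trem2 at 13.1 against 26.2 and Cd68 at 31.6 against 50.5 CPM. Monocyte-derived macrophage genes fell in 9 of 13, and in 10 adjusted over the list alone (camera 5.22e-07, adjusted p = 0.146 with an estimated correlation). Ccr2 was at log2 -0.93. Kupffer cell genes fell in 6 of 14, 7 lower and 1 higher adjusted over the list alone (camera 0.00351, adjusted p = 0.403 with an estimated correlation). In T and NK cell and dendritic cell lists 0 genes passed, also adjusted over the list alone, with medians of 0.40 (camera 0.0768) and -0.39 (camera 0.0182, adjusted p = 0.459 with an estimated correlation). Chemokines had 6 of 22 lower and 1 higher, also adjusted over the list alone (camera 0.139). Ccl2 was at 2.66 ± 1.39 against 5.78 ± 1.44 CPM. Interferon genes fell in 2 of 21, also adjusted over the list alone (camera 0.0037, adjusted p = 0.423 with an estimated correlation).

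Cholangiocyte genes fell in 6 of 17, also adjusted over the list alone (camera 2.34e-05, adjusted p = 0.273 with an estimated correlation), and Krt19 was at 3.64 against 5.07 CPM (adjusted p = 0.302). Endothelial genes fell in 6 of 16, also adjusted over the list alone (camera 0.00194, adjusted p = 0.321 with an estimated correlation). Cell cycle genes fell in 10 of 24 and rose in 1 (the thymidine kinase gene Tk1), 16 and 1 adjusted over the list alone (camera 7.39e-08, adjusted p = 0.0859 with an estimated correlation). Mki67 was at 10.2 ± 5.59 against 18.3 ± 3.41 CPM. Oncofetal genes fell in 4 of 10, and in 5 adjusted over the list alone (camera 0.000173, adjusted p = 0.146 with an estimated correlation). Ly6d was at 24.6 ± 12.4 against 97.7 ± 22.5 CPM. The p53 list had 6 of 19 lower and 1 higher, 6 and 2 adjusted over the list alone (camera 0.00574, adjusted p = 0.152 with an estimated correlation).

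Hepatocyte identity genes rose in 16 of 18, also adjusted over the list alone (camera 3.46e-13, adjusted p = 0.0516 with an estimated correlation). Alb was at 52200 ± 5890 against 35700 ± 5930 CPM. Pericentral genes rose in 10 of 15 and fell in 1, also adjusted over the list alone (camera 3.09e-05, adjusted p = 0.0859 with an estimated correlation). Cyp2e1 was at log2 0.84. Periportal genes rose in 9 of 15 and fell in 1, 9 and 2 adjusted over the list alone (camera 0.000305, adjusted p = 0.216 with an estimated correlation). Hal was at 0.95. Bile acid genes rose in 14 of 22 and fell in 1, 15 and 1 adjusted over the list alone (camera 2.76e-06, adjusted p = 0.117 with an estimated correlation); the gene that fell was the basolateral exporter Abcc4 (log2 -1.47). Cyp7a1 was at 211 ± 146 against 111 ± 47.2 CPM, with an adjusted p = 0.0459 whose call was lost under RLE and upper-quartile scaling, without the filter and in the blocked and joint fits. Xenobiotic genes rose in 12 of 22 and fell in 2, 12 and 4 adjusted over the list alone (camera 0.00234, adjusted p = 0.253 with an estimated correlation). Fatty acid oxidation genes rose in 7 of 24 and fell in 1, 9 and 3 adjusted over the list alone (camera 0.00347, adjusted p = 0.423 with an estimated correlation), led by the microsomal hydroxylase Cyp4a14 at 658 ± 197 against 211 ± 130 CPM. Lipid droplet genes divided, 7 higher and 7 lower of 22, 7 and 9 adjusted over the list alone (camera 0.262), with the triglyceride synthesis gene Dgat2 higher by log2 0.41. De novo lipogenesis genes rose in 3 of 19, also adjusted over the list alone (camera 0.00802, adjusted p = 0.478 with an estimated correlation), while Scd1 was at 35500 ± 6580 against 33800 ± 10500 CPM (adjusted p = 0.779) and Fasn at log2 0.17 (adjusted p = 0.747). Cholesterol synthesis genes rose in 5 of 24, also adjusted over the list alone (camera 0.00373, adjusted p = 0.478 with an estimated correlation), and Hmgcr was at 68.2 ± 20.4 against 49.9 ± 17.8 CPM (adjusted p = 0.126). Efflux genes had 6 of 15 higher and 5 lower, 9 and 5 adjusted over the list alone (camera 0.49). The exporters Abcg5 and Abcg8 were at log2 0.62 and 0.69. Among the larger rises were those of Mup11, Cyp2b10, Sult2a8, Slc22a26 and Acot3 (log2 2.48, 2.34, 1.85, 1.81 and 1.74), and among the larger falls those of Elovl7, Cbr3, Gsta1 and Themis (-2.54, -2.25, -2.15 and -2.10) with Ly6d.

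For semaglutide against MASH vehicle at 12 weeks, edgeR called 1648 genes higher and 1280 lower (21.5% of 13606, smallest adjusted p = 8.4e-09), and 74 and 169 changed more than 2-fold. Upper-quartile scaling gave 1294 and 1537 (45.7% higher against 56.3%). Replicates 1 to 6 alone gave 955 genes and replicates 7 to 10 alone gave 1042. Over the genes called in the full result, of which each set is a part, the correlations with it were 0.98 and 0.97. These are also high by construction. Camera called 27 of 41 lists, none with an estimated correlation, and fry called 26.

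The 24-week comparison put the same question to the longer treatment. Col1a1 fell from 119 ± 33.6 (n = 7) to 42.3 ± 20.7 CPM (n = 8), a log2 fold change of -1.49 ± 0.30 (adjusted p = 0.0014). Gpnmb fell from 102 ± 21.6 to 29.5 ± 14.4 CPM (log2 -1.79 ± 0.26, adjusted p = 5.19e-05) and Cidec from 98 ± 24.1 to 34.9 ± 14.1 CPM (log2 -1.48, adjusted p = 0.00162). Mki67 fell from 13.6 ± 2.38 to 5.26 ± 1.74 CPM (log2 -1.36, adjusted p = 0.00408). Slc10a1 rose from 167 ± 31.1 to 412 ± 83 CPM (log2 1.30, adjusted p = 4.78e-06).

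Matrix genes fell in 25 of 32, and in 29 adjusted over the list alone (camera 2.18e-18, adjusted p = 0.114 with an estimated correlation), with Nid1, a basement membrane linker, at log2 -1.66. Matrix turnover genes fell in 13 of 18, and in 14 adjusted over the list alone (camera 3.08e-10, and 0.0407 with an estimated correlation). The collagenase Mmp13 was at log2 -2.60. Stellate cell genes fell in 5 of 19, 8 lower and 1 higher adjusted over the list alone (camera 0.00404, adjusted p = 0.24 with an estimated correlation), and Acta2 was at 4.86 against 7.37 CPM (adjusted p = 0.0841). Lipid-associated macrophage genes fell in 13 of 19, and in 16 adjusted over the list alone (camera 5.03e-11, adjusted p = 0.103 with an estimated correlation). Spp1 was at 91.6 ± 37.4 against 264 ± 106 and Trem2 at 13.7 ± 4.97 against 39.4 ± 21.2 CPM. Monocyte-derived macrophage genes fell in 3 of 14, also adjusted over the list alone (camera 1.21e-05, adjusted p = 0.282 with an estimated correlation), and in 11 without the 4 set-apart libraries. Kupffer cell genes had 1 of 14 higher (Marco, whose call was lost in 5 alternatives) and 0 adjusted over the list alone (camera 0.161), with a median of -0.43 and a mean of 0.04. T and NK cell genes had 0 calls, also adjusted over the list alone (camera 0.775), and dendritic cell genes 1 lower and 0 adjusted over the list alone (camera 0.00417, adjusted p = 0.344 with an estimated correlation). Chemokines had 7 of 22 lower and 1 higher, 9 and 2 adjusted over the list alone (camera 0.000905, adjusted p = 0.326 with an estimated correlation), and 12 lower without the 4 set-apart libraries. Interferon genes fell in 5 of 21, also adjusted over the list alone (camera 0.000201, adjusted p = 0.468 with an estimated correlation), and in 11 without the 4 set-apart libraries, with the antiviral gene Rsad2 at log2 -2.27. Cholangiocyte genes fell in 8 of 16, and in 11 adjusted over the list alone (camera 7.75e-06, adjusted p = 0.275 with an estimated correlation). Endothelial genes had 3 of 16 lower and 1 higher, also adjusted over the list alone (camera 0.161).

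Cell cycle genes fell in 20 of 23 and rose in 1 (Tk1), also adjusted over the list alone (camera 1.93e-12, and 0.0407 with an estimated correlation). Plk1 was at log2 -1.71. Oncofetal genes fell in 10 of 12, also adjusted over the list alone (camera 2.03e-08, and 0.0407 with an estimated correlation). Ly6d was at 15.6 ± 9.88 against 139 ± 50.6 CPM. The p53 list had 3 of 19 lower and 5 adjusted over the list alone (camera 0.00949, adjusted p = 0.173 with an estimated correlation), and 9 without the 4 set-apart libraries. Hepatocyte identity genes rose in 14 of 18, and in 17 adjusted over the list alone (camera 5.13e-08, and 0.0407 with an estimated correlation). Alb was at 71200 ± 18100 against 41700 ± 5240 CPM. Pericentral genes rose in 7 of 15 and fell in 2, 8 and 2 adjusted over the list alone (camera 0.00672, adjusted p = 0.308 with an estimated correlation), and periportal genes rose in 7 and fell in 1 of 15, 8 and 1 adjusted over the list alone (camera 0.00767, adjusted p = 0.24 with an estimated correlation). Bile acid genes rose in 10 of 22 and fell in 2, 12 and 3 adjusted over the list alone (camera 0.00743, adjusted p = 0.24 with an estimated correlation). The oxysterol hydroxylase Cyp7b1 was at log2 1.05 and Abcc4 at -2.96. De novo lipogenesis genes rose in 4 of 19, also adjusted over the list alone (camera 0.00743, adjusted p = 0.512 with an estimated correlation), and in 8 without the 4 set-apart libraries. Srebf1, a regulator of lipid synthesis, rose to 725 ± 250 from 410 ± 38.8 CPM (adjusted p = 0.00335) and Scd1 was at 20400 ± 5210 against 20100 ± 3590 CPM (adjusted p = 0.941). Cholesterol synthesis genes rose in 10 of 24, and in 11 adjusted over the list alone (camera 0.000329, adjusted p = 0.326 with an estimated correlation). Tm7sf2 was at log2 0.90 and Hmgcr at 0.29 (adjusted p = 0.387). Lipid droplet genes had 4 of 22 higher and 6 lower, 5 and 6 adjusted over the list alone (adjusted p = 0.843 with an estimated correlation), with a median of 0.01 that turned to -0.03 under RLE and -0.07 under upper-quartile scaling. Efflux genes had 5 of 15 higher and 3 lower, also adjusted over the list alone (camera 0.346), oxidation genes 7 of 24 higher and 1 lower, also adjusted over the list alone (camera 0.106), and xenobiotic genes 7 of 22 higher and 6 lower, 9 and 6 adjusted over the list alone (camera 0.217, with a median of 0.30 and a mean of -0.02). Cbr3, Elovl7 and Gsta1 were among the larger falls (log2 -4.52, -4.39 and -3.61), and Hsd3b5 and Mup11 among the larger rises (5.55 and 4.69) with a wide spread between libraries (Mup11 at 256 ± 618 CPM).

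In the edgeR test of semaglutide against MASH vehicle at 24 weeks, 1422 genes rose and 1252 fell (19.7% of 13548), and 176 and 502 changed more than 2-fold. Without the 4 set-apart libraries, 1829 rose and 2091 fell. Upper-quartile scaling gave 924 higher and 1478 lower (38.5% higher against 53.2%), the analysis without the filter gave 814 and 1177, and limma voom with sample quality weights gave 3189 and 2525. Camera called 24 of 41 lists, 4 of them with an estimated correlation, and fry called 22.

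**Figure D3:**
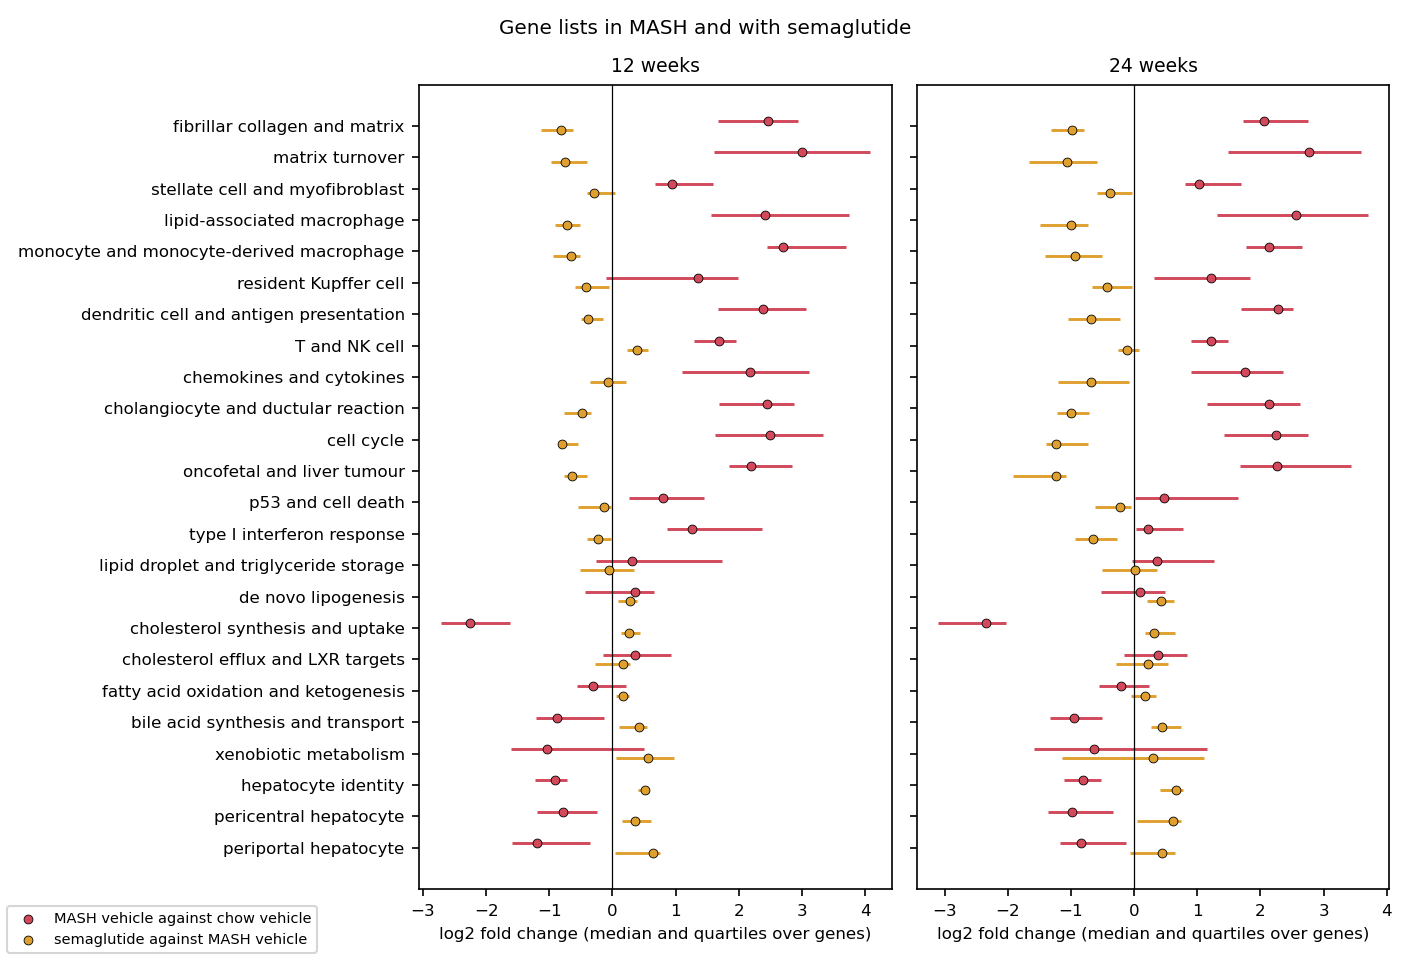
Log2 fold changes (horizontal axis) of 24 gene lists at 12 and 24 weeks, with a point for the median over genes and a line for the quartiles, in red for MASH against chow and in yellow for semaglutide against MASH. The matrix list has medians of 2.46 and -0.81 at 12 weeks and 2.05 and -0.99 at 24 weeks, while the cholesterol synthesis list has medians of -2.25 and 0.27 and of -2.35 and 0.32.

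Genes that changed in MASH were next followed under treatment, to see which moved back. At 12 weeks 2686 genes moved back, 1191 of them higher in MASH and lower with semaglutide and the rest the reverse. Among the former were S100a11 (log2 3.29 in MASH and -1.55 with semaglutide), Col5a1 (1.86 and -0.89) and the galectin gene Lgals1 (1.85 and -0.91). Among the latter were the coagulation factor gene F7 (-1.19 and 0.78) and the peroxisomal lyase Hacl1 (-2.21 and 1.04). At 24 weeks these numbers were 1099 and 1175, with Elovl7 (6.10 and -4.39), the membrane-binding Anxa2 (3.80 and -2.07) and the vasopressin receptor Avpr1a (-3.16 and 1.63). Of the genes selected at 24 weeks, Ctps, Gipc2 and Paox were not called between semaglutide and chow (adjusted p = 0.711, 0.133 and 0.12), and the others were. The balance of the directions depended on scaling, with 1342 and 1237 under RLE at 12 weeks and 1251 and 914 at 24 weeks. The 24-week fit without the filter gave 1047 and 675, and that without the 4 set-apart libraries 1746 and 1460. Most of the 12-week genes still differed from chow under semaglutide in the MASH direction: 934 of the 1191 higher in MASH (78.4%) and 935 of those lower (62.5%). At 24 weeks the same held for 530 of 1099 (48.2%) and 262 of 1175 (22.3%). The 24-week shares rest on the 2718 genes of semaglutide against chow, which became 3794 without chow replicate 7 and 2085 without semaglutide replicate 4. Of simulated 1.5-fold changes, 26.9% and 35.8% were found in the semaglutide and MASH comparisons at 24 weeks, against 66.7% and 76.9% at 12 weeks, so the shares of the durations are not comparable. Genes that moved further from chow numbered 27 at 12 weeks and 14 at 24 weeks, among them Abcg5, which rose in MASH and again with semaglutide at both durations (1.55 and 0.62, then 1.43 and 0.59).

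Both comparisons share the MASH vehicle libraries, so some opposite movement arises by construction. Lists drawn independently would share 399.2 and 505.1 genes at 12 weeks and 270.6 and 332.5 at 24 weeks. In 20 simulations of unchanged groups, 0 genes passed in either comparison. Their count therefore does not show how many opposite calls the shared libraries add where genes do change. The correlation across genes, which are not independent replicates, was -0.711 at 12 weeks (Spearman -0.739) and -0.81 at 24 weeks (Spearman -0.762), against simulated means of -0.488 and -0.523. The covariance was -0.28 against a simulated -0.0182 at 12 weeks, and -0.426 against -0.0296 at 24 weeks. With the MASH vehicle libraries split so that each served only 1 of the comparisons, 1983 and 973 genes moved back at 12 weeks and 593 and 962 at 24 weeks. With the MASH effect taken from the other cohort, which shares no library, the numbers were 2206 and 2298. For genes chosen as changed more than 2-fold in the other cohort, the median semaglutide change was 26.1% of the MASH change at 12 weeks for genes higher in MASH and 35.1% for genes lower, and 42.9% and 52.2% at 24 weeks.

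**Figure D4:**
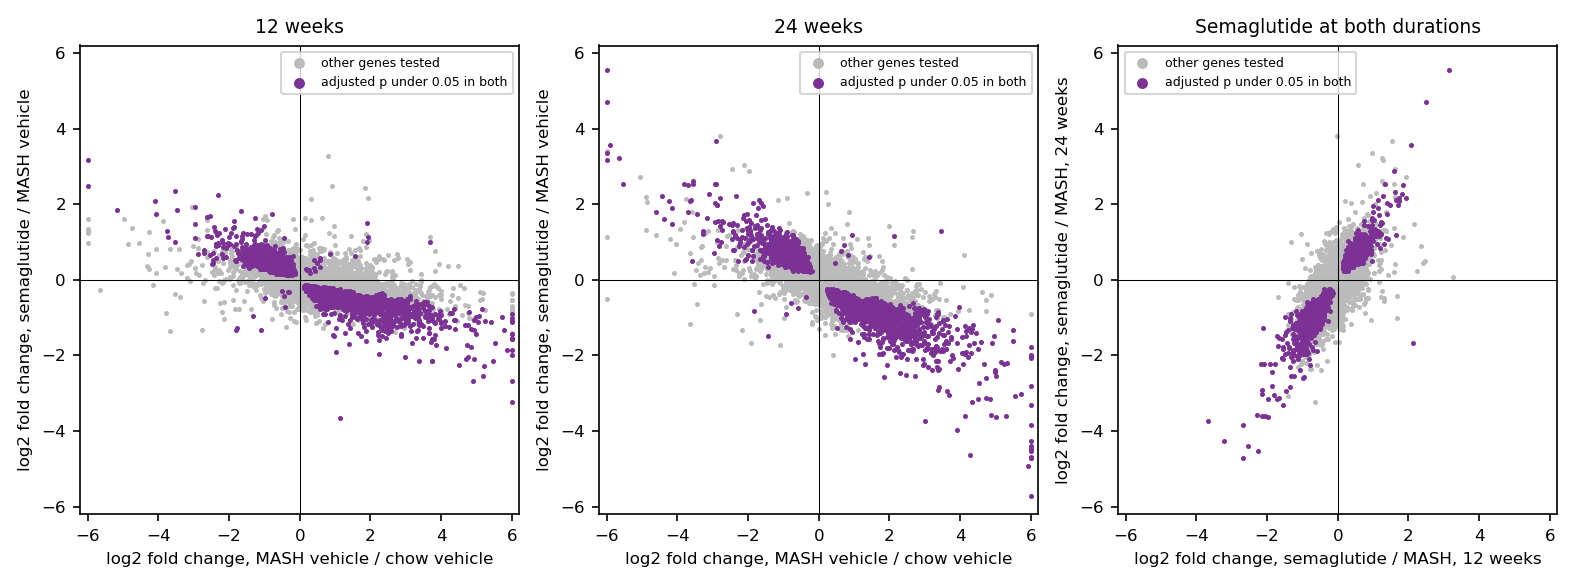
Log2 fold changes of each gene tested, with MASH against chow on the horizontal axis and semaglutide against MASH on the vertical axis at 12 weeks (left) and 24 weeks (middle), and the semaglutide change at 12 against 24 weeks (right). Purple marks an adjusted p under 0.05 in both comparisons, and values beyond 6 are drawn at the edge of the axis. The first pair of panels slopes downward (r = -0.711 and -0.81) and the last slopes upward (r = 0.79).

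Semaglutide was also set against chow, to show what differed from chow after treatment. Matrix genes were higher in 29 of 32 at 12 weeks, also adjusted over the list alone (camera 2.01e-15, adjusted p = 0.0876 with an estimated correlation), and in 23 at 24 weeks, 24 adjusted over the list alone (camera 8.2e-15, adjusted p = 0.114 with an estimated correlation). Lipid-associated macrophage genes were higher in 17 of 19 at 12 weeks, 18 adjusted over the list alone (camera 4.88e-12, adjusted p = 0.0694 with an estimated correlation), and in 15 at 24 weeks, 17 adjusted over the list alone (camera 2.31e-14, and 0.0461 with an estimated correlation). Chow replicates 5 and 7 at 24 weeks lay above the mean of the other chow libraries in 32 and 22 of 32 matrix genes (median log2 difference 0.869 and 0.122). For the macrophage list these medians were 0.925 and 1.03. Cholesterol synthesis genes were lower in 23 of 24 at 12 weeks (camera 3.28e-27, adjusted p = 0.0624 with an estimated correlation) and in 24 of 24 at 24 weeks (camera 6.34e-41, and 0.00177 with an estimated correlation), the same adjusted over the list alone, with medians of -2.03 and -2.05. Hepatocyte identity genes were lower in 13 of 18 and higher in 1 at 12 weeks, also adjusted over the list alone (camera 5.21e-06, adjusted p = 0.125 with an estimated correlation). At 24 weeks they were lower in 4 and higher in 1, 6 and 2 adjusted over the list alone (camera 0.0209, adjusted p = 0.272 with an estimated correlation), or lower in 8 and higher in 2 without the 4 set-apart libraries. Cell cycle genes were higher in 21 of 24 at 12 weeks, also adjusted over the list alone (camera 7.62e-06, adjusted p = 0.103 with an estimated correlation), and in 15 of 23 at 24 weeks, 18 adjusted over the list alone (camera 4.49e-08, adjusted p = 0.0706 with an estimated correlation). Interferon genes were higher in 18 of 21 at 12 weeks, 18 higher and 1 lower adjusted over the list alone (camera 1.14e-05, adjusted p = 0.201 with an estimated correlation). At 24 weeks they had 0 calls, with a median of -0.33 and an upward camera statistic (adjusted p = 0.257), and 14 higher without chow replicates 5 and 7 at 24 weeks. By edgeR, 3522 genes were higher and 2868 lower than chow at 12 weeks (47% of genes tested, 5257 in replicates 1 to 6 and 2756 in replicates 7 to 10), and 1588 and 1130 at 24 weeks (20.1%). For semaglutide against chow vehicle at 24 weeks, the total of 2718 became 4556 without the 4 set-apart libraries and 5021 in voom, and upper-quartile scaling gave 1796 higher and 739 lower (70.8% higher against 58.4%).

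The durations were compared last, to ask whether longer treatment acted differently. Of 13205 genes tested in both cohorts, 843 rose and 729 fell with semaglutide at both durations and 1 changed in opposite directions, where independent lists would share 174 and 117.7. The correlation of the semaglutide changes across genes was 0.79 (Spearman 0.754), and 0.254 without the filter on low counts. For MASH against chow, 2711 genes rose and 2603 fell at both durations and 6 went in opposite directions (r = 0.935, Spearman 0.891). The test of the difference itself called 0 of 14546 genes for semaglutide (edgeR, smallest adjusted p = 0.229), where 788 had an unadjusted p under 0.05 and 727 are expected by chance. DESeq2 called 1 gene and voom 27. Gpnmb differed by -0.82 ± 0.36 on the log2 scale (adjusted p = 0.895) and Col1a1 by -0.33 ± 0.36 (adjusted p = 0.91). The MASH effect differed in 0 genes (smallest adjusted p = 0.0824, 1233 with an unadjusted p under 0.05), with 9 by DESeq2 and 19 by voom. Camera called 13 of 42 lists for the semaglutide difference and 16 for the MASH difference, none with an estimated correlation, and fry called 0 and 2. For example, the lipid-associated macrophage list had a median difference of -0.38 under semaglutide (camera 0.000137, adjusted p = 0.682 with an estimated correlation). Duration and cohort cannot be told apart in any of these values.

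By position in GRCm38, Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042 and Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929. Slc10a1 (ENSMUSG00000021135) lies on chromosome 12 from 80953183 to 80968705, Alb (ENSMUSG00000029368) on chromosome 5 from 90460897 to 90476602, Hmgcr (ENSMUSG00000021670) on chromosome 13 from 96648967 to 96670936, and Sqle (ENSMUSG00000022351) on chromosome 15 from 59315077 to 59331192. All 6 are annotated as protein-coding genes, and values are totals over the whole gene.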

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

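The tests of a mislabelled and of a mixed chow library, of macrophage against other cell-type lists and of the interferon list without chow replicates 5 and 7 were chosen after seeing the data, while the depth comparison and the draws of smaller groups were set before. A library was listed for a gene when the gap to its nearest neighbour was large against the range of its group (Dixon's ratio). For normally distributed values, chance alone gives this in about 1 in 20 groups. Of 126 sets of values 13 held such a library, where 6.3 would be expected on that basis. Most sets were CPM on a linear scale, which need not be normal, and most listed values were the highest of their group. The expected number may therefore not hold. A first test of chow replicate 7, its position on an axis from chow (0) to MASH (1), gave 0.475 and was undecided, and the cholesterol list took its place.

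Chow replicate 7 at 24 weeks lay apart from its group, close to semaglutide libraries. Its cholesterol synthesis list stood at 7.74 log2-CPM, against 7 to 7.6 in other chow and 4.79 to 5.07 in MASH libraries, so a mislabelled MASH library could be excluded. In it 16 of 21 interferon genes exceeded the highest MASH library (Isg15 at 89.8 against at most 23.5 CPM), while Gpnmb was at 0.616 and Cidec at 0.231 CPM, which excludes admixed MASH RNA. Its depth of 15 M counts lay within the 12.1 to 17.9 of the other chow libraries. Its share of counts from mitochondrially encoded genes was 1.76%, against 2.64% to 4.57% in the other 24-week chow libraries. MASH replicate 3 (1.29%) and semaglutide replicate 2 (1.37%), also set apart, were lowest in their groups. Chow replicate 7 and these libraries also lay lowest on the second principal component (-35.78, -37.63 and -39.41). Semaglutide replicate 8, also set apart, had the highest share of its group (3.39%). No biological explanation was tested, although in chow replicate 7 Saa1 at 1930 and Lcn2 at 591 CPM could point to an acute inflammatory state. Chow replicate 5 shared this in part, with Saa1 at 304 and Lcn2 at 164 CPM. The remaining chow libraries had at most 34.9 and 5.69 CPM. Replicate 5 lay above their mean in 20 of 21 acute phase genes and 21 of 21 interferon genes (median log2 difference 1.23 and 0.796).

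The interferon list had 20 genes higher and 1 lower in MASH at 12 weeks, and 5 higher and 1 lower at 24 weeks. Without chow replicates 5 and 7 at 24 weeks 19 were higher, and without replicate 7 alone 18, against 5 when any other chow library was left out. In 20 draws of 8, 7 and 8 libraries at 12 weeks 19 to 21 interferon genes passed the threshold in either direction, so smaller groups could not account for the difference. The lower number is therefore likely to come from chow replicate 7.

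The fall of the lipid-associated macrophage list with semaglutide might reflect a lower share of all cells other than hepatocytes. At 12 weeks the list's change lay 0.443 below that of the endothelial list (permutation p = 0.00392, 9 of 10 libraries). It lay 1.05 below that of the T and NK cell list (permutation p = 0.00021, 10 of 10). At 24 weeks the differences were -0.865 (exact p = 0.000155) and -0.96 (exact p = 0.00155), each in 8 of 8 libraries. The T and NK cell list had no call at either duration, which was known when the tests were chosen. In MASH its mean lay 5.91 and 6.07 log2 units below the macrophage list at 12 and 24 weeks. At such levels the prior count compresses falls, so that comparison decides nothing. The endothelial results were also known, so those p-values show only that the macrophage list fell further than that list. The smallest median of the macrophage list under RLE or upper-quartile scaling was -0.75 at 12 and -1.04 at 24 weeks. These scalings shifted the log2 fold changes of all genes by medians of -0.025 and -0.034 at 12 weeks. At 24 weeks the shifts were -0.043 and -0.073. Shifts this small could not have undone the fall, so the test decides nothing about the scaling factors. Fewer macrophages, less active ones or lower levels of these genes in other cells remain open, and bulk RNA cannot separate them. The list shares Spp1 with the cholangiocyte list and Cd36 with the lipid droplet list.

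Chow replicate 5 at 24 weeks had Col1a1 at 14.1 CPM (others 4.26 to 8.85) and Col3a1 at 42.5 CPM (13.2 to 19.3). Chow replicate 8 at 24 weeks had Fgf21 at 4.4 CPM (0.162 to 1.86). MASH replicate 3 at 24 weeks had Trem2 at 86.4 CPM (26 to 39.7). Semaglutide replicate 2 at 24 weeks had Col3a1 at 18.8 CPM (54.6 to 86.6). Semaglutide replicate 8 at 24 weeks had Timp1 at 5.7 CPM (1.04 to 2.87) and Ccl2 at 5.16 CPM (0.426 to 2.65). Semaglutide replicate 4 at 24 weeks had Acta2 at 9.39 CPM (2.76 to 5.65). Chow replicate 7 at 12 weeks had Col1a1 at 15.1 CPM (4.66 to 8.85), and chow replicate 4 had Timp1 at 0.254 CPM where the others had 0. Semaglutide replicate 10 at 12 weeks had Gpnmb at 144 CPM (30.4 to 88.1) and Fgf21 at 25.3 CPM (0.548 to 4.57). Semaglutide replicate 5 at 12 weeks had Mki67 at 23.2 CPM (4.68 to 14.5). The MASH effect on the periportal list and on the NRF2 list differed between durations by fry (adjusted p = 0.0217 each), with an adjusted p = 0.15 each by camera with an estimated correlation.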

How the results depend on the processing

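The replicate sets, leave-one-out fits and fits without set-apart libraries were chosen after seeing the data. Where no cause is named, the cause was not tested.

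With 12-week replicates 7 to 10 only, MASH against chow gave 5541 genes, semaglutide against MASH 1042 and semaglutide against chow 2756. With replicates 1 to 6 only, semaglutide against MASH gave 955. For semaglutide against MASH vehicle at 24 weeks, limma voom gave 5714, with 2615 of the 2674 edgeR genes in the same direction. For semaglutide against chow vehicle at 24 weeks voom gave 5021, and edgeR without the 4 set-apart libraries gave 4556, against 2718 with them.

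The semaglutide difference between durations had 1 gene by DESeq2 and 27 by voom. The MASH difference had 2 without the filter, 9 by DESeq2, 19 by voom and 4 without the set-apart libraries. Of 106 camera calls of gene lists in MASH against chow and semaglutide against MASH, 11 held with an estimated correlation. Acute phase genes reversed to a median semaglutide difference of 0.0151 without the set-apart libraries. Over the genes selected for naming, 356 calls at an adjusted p under 0.05 were lost in an alternative and 27 gained. In 6939 cases the call status was the same. The sign reversed in 0 cases with a call in either fit, while sign changes without a call counted as the same. Of the lost calls, 79 and 92 came from 12-week replicates 1 to 6 and 7 to 10 alone, which use fewer libraries.

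Genes that moved back numbered 973 with even-numbered MASH libraries against chow at 12 weeks, and 593 and 962 in the divisions at 24 weeks. Each division uses fewer libraries per comparison.

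Leaving out 1 library at a time gave 8217 to 8378 genes for MASH at 12 weeks and 5250 to 6288 at 24 weeks. For semaglutide against MASH it gave 2480 to 3227 and 1837 to 3739, and for semaglutide against chow 6037 to 6482 and 2085 to 3794.

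A block for the replicate number gave 1 gene for the MASH difference between durations. Libraries with the same number showed little tendency to deviate together from their group means. Their median correlation was 0.0063 at 12 weeks and -0.048 at 24 weeks. It exceeded 0.1 in 1 of 30 such pairs at 12 weeks and in 5 of 22 at 24 weeks (highest 0.4). Neither the block nor these values can show a pairing or batch that does not follow the replicate number.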

Other observations

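The comparison of how far the matrix and cholesterol lists returned to chow was chosen after seeing the data, and the random divisions of libraries were set before.

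Counts adjusted over the list alone are given here where they differ. All 24 oxidative phosphorylation genes fell in MASH at 12 weeks, also adjusted over the list alone (camera 1.71e-11, adjusted p = 0.122 with an estimated correlation), and 19 rose with semaglutide, 24 adjusted over the list alone (camera 3.66e-09, adjusted p = 0.216 with an estimated correlation). At 24 weeks 9 fell, 8 adjusted over the list alone (camera 0.00255, adjusted p = 0.467 with an estimated correlation), and 10 rose with semaglutide, 11 adjusted over the list alone (camera 7.15e-06, adjusted p = 0.326 with an estimated correlation). Without the 4 set-apart libraries, 19 fell in MASH. A list of sex-biased genes held major urinary proteins, a serpin, Cyp and Sult enzymes and other genes. Its genes fell in 14 of 19 at 12 weeks and rose in 3, also adjusted over the list alone (camera 2.51e-05, adjusted p = 0.152 with an estimated correlation). They rose in 6 with semaglutide and fell in 1, 8 and 2 adjusted over the list alone (camera 0.00532, adjusted p = 0.403 with an estimated correlation). At 24 weeks 12 of 20 fell and 1 rose, 13 and 3 adjusted over the list alone (camera 0.00282, adjusted p = 0.237 with an estimated correlation), and 9 rose with semaglutide, 13 adjusted over the list alone (camera 0.00471, adjusted p = 0.308 with an estimated correlation). The last was 5 without the 4 set-apart libraries. The sex-biased list was not divided by the sex in which its genes are higher, so these counts do not show which class changed.

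Oxidative stress genes under NRF2 rose in 15 of 23 and fell in 8 in MASH at 12 weeks (camera 0.124), and 8 fell and 3 rose with semaglutide, 12 and 3 adjusted over the list alone (camera 0.00194, adjusted p = 0.174 with an estimated correlation), with Srxn1 at log2 -1.24. At 24 weeks 13 rose and 4 fell (camera 0.000846, adjusted p = 0.201 with an estimated correlation), and 8 fell and 1 rose with semaglutide, 11 and 1 adjusted over the list alone (camera 2.73e-05, adjusted p = 0.173 with an estimated correlation). Lysosome genes rose in 17 of 24 and fell in 3 at 12 weeks (camera 0.000202, adjusted p = 0.105 with an estimated correlation), and 12 fell and 2 rose with semaglutide, 14 and 4 adjusted over the list alone (camera 5.79e-05, adjusted p = 0.103 with an estimated correlation). At 24 weeks 13 rose and 3 fell, 14 and 3 adjusted over the list alone (camera 0.000792, adjusted p = 0.0807 with an estimated correlation), and 7 fell and 1 rose with semaglutide, 10 and 2 adjusted over the list alone (camera 0.00629, adjusted p = 0.24 with an estimated correlation).

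Unfolded protein response genes fell in 14 of 20 and rose in 2 at 12 weeks, 15 and 2 adjusted over the list alone (camera 0.0106, adjusted p = 0.331 with an estimated correlation), and fell in 13 and rose in 2 at 24 weeks, 15 and 2 adjusted over the list alone (camera 0.0131, adjusted p = 0.458 with an estimated correlation). With semaglutide 2 rose and 2 fell (camera 0.891), then 1 and 1, 0 and 1 adjusted over the list alone (camera 0.548). Circadian clock genes fell in 7 of 16 and rose in 1 (camera 0.173), then fell in 6 (camera 0.128), and with semaglutide rose in 5, 7 adjusted over the list alone (camera 0.0209, adjusted p = 0.216 with an estimated correlation) and 3 (camera 0.0468, adjusted p = 0.284 with an estimated correlation). Glucose metabolism genes had 5 of 26 higher and 14 lower (camera 0.609), then 5 and 9 (camera 0.972). With semaglutide they had 10 higher and 3 lower, 10 and 4 adjusted over the list alone (camera 0.0729), then 6 and 3, 8 and 3 adjusted over the list alone (camera 0.172). Acute phase genes had 11 of 21 higher and 8 lower, 11 and 9 adjusted over the list alone (camera 0.184), then 1 and 7 (camera 0.924), or 10 and 4 without chow replicates 5 and 7 at 24 weeks. With semaglutide they had 8 higher and 2 lower, 9 and 2 adjusted over the list alone (camera 0.0768), then 6 higher (camera 0.17).

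B and plasma cell genes had 3 of 10 higher and 2 lower in MASH (camera 0.505), then 1 and 2 of 11 (camera 0.825), and 0 and 1 calls with semaglutide (camera 0.934 and 0.939). Neutrophil genes had 2 of 3 higher (camera 0.141), then 1 (camera 0.365), and 1 lower and 0 calls with semaglutide (camera 0.218 and, with an estimated correlation, 0.826). Mitochondrially encoded genes fell in 7 of 7 in MASH at 12 weeks (camera 5.96e-05, adjusted p = 0.155 with an estimated correlation) and in 3 at 24 weeks, 4 adjusted over the list alone (camera 0.113). With semaglutide 4 rose, 6 adjusted over the list alone (camera 0.00812, adjusted p = 0.403 with an estimated correlation), then 0 (camera 0.939). Ribosomal protein genes fell in 19 of 21 at 12 weeks (camera 8.18e-05, adjusted p = 0.302 with an estimated correlation) and in 0 at 24 weeks (camera 0.465). With semaglutide 1 rose, 0 adjusted over the list alone (camera 0.0639), then 0 (camera 0.00673, adjusted p = 0.688 with an estimated correlation). Immediate early genes had 6 of 16 higher and 5 lower (camera 0.511), then 4 and 5 of 15 (camera 0.639), and with semaglutide 2 and 2 (camera 0.365), then 1 and 4 (camera 0.172). Erythroid genes had 1 of 6 lower in MASH at each duration (camera 0.511 and 0.414) and 0 calls with semaglutide (camera 0.383 and 0.346). Adipose genes had 3 of 6 higher and 2 lower (camera 0.627), then 2 and 2 (camera 0.36), and with semaglutide 2 and 2 (camera 0.218), then 1 and 2 (camera 0.548). Histone genes had 1 of 4 higher and 1 lower at each duration (camera 0.969 and 0.972) and 0 calls with semaglutide (camera 0.218 and 0.797). The 1 exocrine pancreas gene was lower (log2 -1.50 and -1.35) and the 2 gut epithelium genes higher in MASH (medians 1.93 and 1.33), with 0 calls for either under semaglutide. Adjusted over the list alone, the pancreas gene fell at 12 weeks and 1 gut gene rose at 24 weeks.

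Random divisions of the libraries into groups of the real sizes asked whether chance could give the counts. The real count was the highest of 40 divisions (as large in 1, itself) in each comparison of groups. It was 8413 against at most 0 for MASH at 12 weeks, 2928 against 2 for semaglutide against MASH and 6390 against 3551 for semaglutide against chow. At 24 weeks it was 6096 against 3146, 2674 against 1040 and 2718 against 3. Counts this large were thus rare among random divisions. With 40 divisions, the real one included, a share below 1 in 40 cannot be shown, so chance is not excluded. For the difference of the semaglutide effect between durations, 17 of 40 divisions had as many genes with an unadjusted p under 0.05 as the real 788 (highest 2549), and for the MASH effect 12 of 40 had as many as the real 1233 (highest 5557). These divisions exchange group labels within each cohort, so an uneven draw carries the effect of semaglutide or of MASH into the difference. They therefore cannot decide whether chance gave the real counts.

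The semaglutide libraries had moved 35.2 ± 12.6% of the way from MASH to chow for the matrix list and 9.41 ± 18.1% for the cholesterol synthesis list at 12 weeks (n = 10, larger for matrix in 9, exact sign-flip p = 0.00391). At 24 weeks the shares were 49.6 ± 19.5% and 14.2 ± 12.1% (n = 8, larger in 7, exact p = 0.0156). The lists were chosen because their medians differed in this way, and the error of the chow and MASH means is not in these p-values, so the test decides nothing about a difference between the lists.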
